A study of Strongylocentrotus purpuratus and Patiria miniata with 4 samples.

How the data were processed

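Tbrain (Tbr) is a T-box transcription factor of echinoderm embryos. Its binding to chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the purple sea urchin Strongylocentrotus purpuratus and the bat star Patiria miniata, a sea star. The 4 samples are 1 immunoprecipitated library and 1 input library (chromatin sequenced without immunoprecipitation) of each species. Per the labels' protocols, embryos were grown at 15 °C to the mesenchyme blastula stage in the sea urchin, at about 24 hours after fertilization, or to the hatched blastula stage in the sea star, at about 30 hours. They were fixed in 1% formaldehyde for 10 minutes, and the chromatin was cut with micrococcal nuclease. Each immunoprecipitation used 50 µg of chromatin and 10 µg of an antibody made against that species' own Tbr protein. Chromatin of 2 to 3 separately fertilized cultures was pooled before the immunoprecipitation, so each species has 1 biological replicate and no spread between replicates can be computed.

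Per the submitters' processing notes, the tools were CASAVA 1.8, Bowtie2 2.2.2, SAMtools 0.1.19 and MACS2 2.1.0; their settings, the genome builds and the peak thresholds are not given in the sources used here. The data analysed are the 2 deposited peak lists, 1 per species, each called on the single ChIP library. The deposited fold enrichment of a peak is the ratio of ChIP signal to local background at the summit. The deposited p-value and q-value columns hold −log10 p and −log10 q against the same background. The deposited score column, by the values, is the whole part of 10 times −log10 q in 100% of the sea urchin peaks and of 10 times −log10 p in 100% of the sea star peaks. The lowest values were a −log10 q of 1.32 in the sea urchin list and a −log10 p of 5.13 in the sea star list, so the lists were cut differently. Peak widths and ranks from the lists are therefore set side by side as descriptions, with no test between species. Starts, ends and summits are 1-based scaffold positions, as the files give them after adding 1 to the start.

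The files state no reads per peak, but these could be computed. In MACS2 the fold enrichment is the summit pileup plus 1 over the background plus 1, and the p-value is the upper Poisson tail of the pileup. For every peak, whole pileups up to 599 were tried and the one that gave the deposited −log10 p was kept. The deposited −log10 p was met within 0.001 in 100% of the peaks of both lists. The largest error was 4.85e-05 in the sea urchin and 0.000151 in the sea star, while the next best pileup was off by at least 0.0109 and 0.00269. The pileup is called ChIP fragments at the summit below, and the background is called scaled input. The scaled input is the highest of 4 values: the genome-wide mean and the input around the summit in a window of 1 fragment, of 1 kb and of 10 kb. Its steps gave 0.572 ChIP reads per input read in the sea urchin and 0.514 in the sea star. With fragment lengths of 96 bp and 84 bp, which are also the smallest peak widths, every scaled input fell on a step of one of these windows or on the genome-wide mean. The genome-wide mean was 1.51 fragments in the sea urchin and 1.77 in the sea star, which is a depth of 15.8 and 21.1 ChIP reads per kb and of 27.6 and 41.0 input reads per kb. These depths are per kb of the genome size set in MACS2, which is not given in the sources used here; another size would scale them. Total reads per library were not used here. Intervals of single pileups are exact Poisson 95% intervals and cover counting error only, since the reads carry no molecular identifiers. Intervals of medians are 95% order-statistic intervals over the peaks of 1 list, and peaks are not replicates.

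Clustering was tested within each list, over scaffolds with 3 or more summits. The share of neighbouring summits at most 1000 bp apart was compared with 1000 random placements of the same number of summits between the first and the last summit of the scaffold, one-sided, so that the smallest p is 0.001. In tests on simulated data the pileup was recovered in 100% of the simulated peaks of each list's size, and 7.5% (sea urchin) and 5% (sea star) of 40 uniform placements were called clustered at 0.05. Alternatives were a higher −log10 q or fold enrichment, merging of nearby intervals, other distances for close summits, equal list lengths and scaffolds with 2 or more peaks; these were fixed before the data were examined. Others, added after seeing the data, left out certain scaffolds or peaks of high scaled input, set 1 −log10 p for both lists, or thinned the sea star fragments to the sea urchin depth, by a share that also rests on these genome sizes. The rule for naming peaks, fixed before the data were examined, was the 10 with the highest −log10 q, the 5 with the highest fold enrichment, the widest peak and the scaffold with most peaks of each species. Other peaks and scaffolds named below were chosen after their values were seen. No genome or annotation of the builds of these files was used here. The planned analyses of gene positions, of 9 gene lists, of 16 binding sites near summits and of genes shared between the species were therefore not run, and no gene is named. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.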

Results

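The study asked where Tbr binds chromatin in early embryos of 2 echinoderms, using an antibody against each species' own protein. The data are 1 list of peaks for the sea urchin at mesenchyme blastula, when the skeleton-forming mesenchyme enters the blastocoel, and 1 for the sea star at hatched blastula. Each list compares 1 ChIP library with the input of its species, without a biological replicate. By the caller's genome-wide mean, the sea urchin library held 15.8 ChIP reads per kb of the genome size set in the caller and the sea star library 21.1.

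Tbr peaks were more numerous in the sea star than in the sea urchin. The sea star list held 13977 peaks on 8491 scaffolds, and the sea urchin list held 3149 peaks on 1199 scaffolds. The ratio of the lists was 4.44 sea star peaks per sea urchin peak. Peaks took up 1454 kb in the sea star and 523 kb in the sea urchin. Of the scaffolds with a peak, 64.4% had a single one in the sea star and 51.8% in the sea urchin. The lists were cut at different thresholds and come from assemblies with different scaffolds, so the counts were also taken at the same significance. At a −log10 p of 5 or more there were 13977 sea star peaks and 2899 sea urchin peaks, a ratio of 4.82. At 10 or more, 12921 and 1040 remained, a ratio of 12.4, and at 20 or more, 2984 and 67, a ratio of 44.5. The ratio thus depended on the limit chosen, and it was above 4 at each of these limits. With 1 library per species, no test across replicates could be made, and species, antibody and stage differ together.

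**Figure D1:**
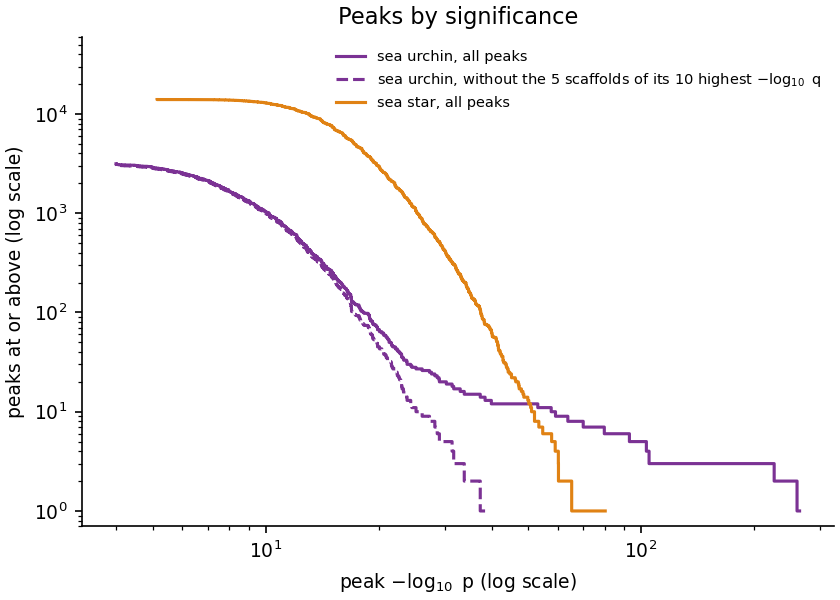
Number of peaks (vertical axis, log scale) at or above each −log10 p (horizontal axis, log scale) in the sea urchin and the sea star list. The dashed line leaves out the 5 sea urchin scaffolds that hold its 10 highest −log10 q. The sea star curve lies above the sea urchin curve at a −log10 p of 10, with 12921 against 1040 peaks, and the sea urchin curve extends further to the right only with those 5 scaffolds included.

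In the deposited lists, sea star peaks were narrower and had a higher fold enrichment over their local background, but the size of the difference in fold enrichment depended on the limit of significance. The median fold enrichment was 6.14 in the sea star (95% interval 6.12 to 6.16 over peaks) and 4.15 in the sea urchin (4.10 to 4.20). Its quartiles were 5.02 and 7.34 in the sea star and 3.43 and 4.97 in the sea urchin. Among peaks with a −log10 q of 10 or more in both lists, the medians were 6.86 in the sea star and 6.53 in the sea urchin. That limit kept 9574 of 13977 sea star peaks and 276 of 3149 sea urchin peaks. The q-value rests on the same pileup and background as the fold enrichment, so a common limit can by itself bring the medians together. In the 3149 sea star peaks with the highest −log10 q the median was 8.12, against 4.15 in all 3149 sea urchin peaks. Over the full lists, the median peak had 26 ChIP fragments at its summit in the sea star and 20 in the sea urchin, over a scaled input of 3.3 and 4.0 fragments. A fold enrichment of 10 or more was reached by 499 sea star peaks and by 23 sea urchin peaks. The median width was 95 bp (94 to 95) in the sea star and 130 bp (128 to 133) in the sea urchin, close to the shortest widths of 84 bp and 96 bp in the lists. At a −log10 q of 10 or more the median widths were 98 bp and 162.5 bp. Choosing peaks this way leaves their edges as each list's own cut drew them, so it does not put the widths on a common limit. Widths of 500 bp or more were found for 49 sea urchin peaks and 1 sea star peak. The median scaled input was 2.64 times the genome-wide mean in the sea urchin and 1.88 times in the sea star, but it cannot fall below that mean.

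**Figure D2:**
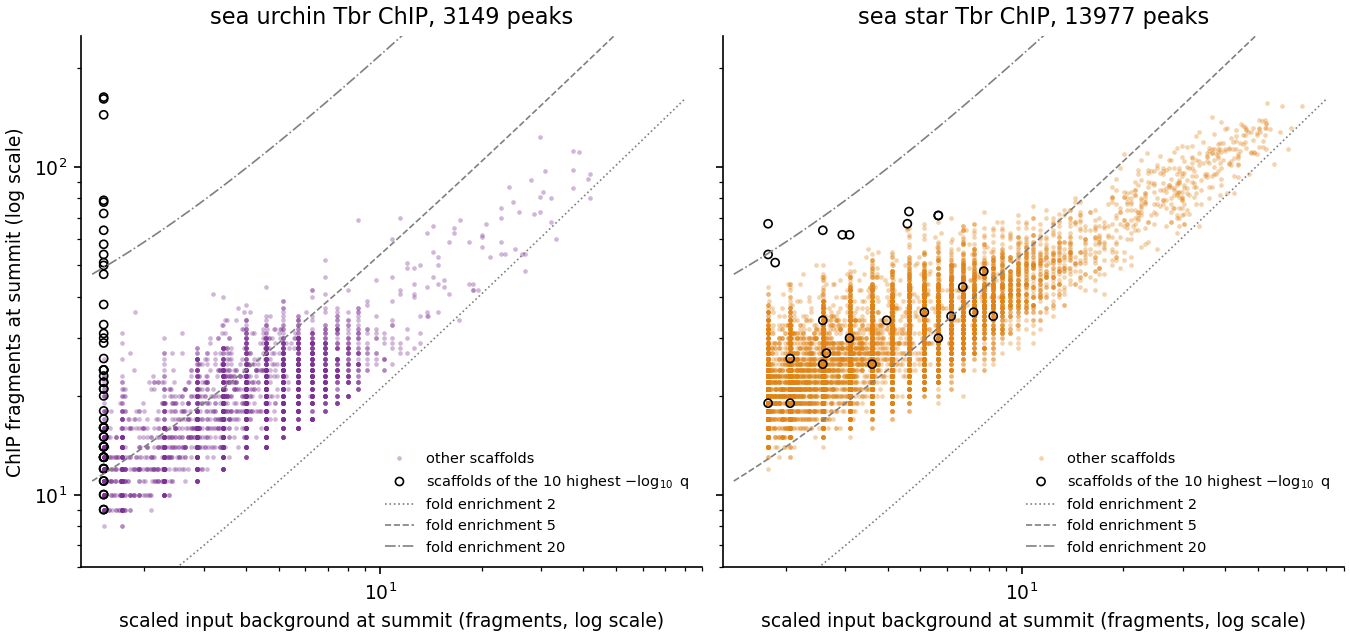
ChIP fragments at the summit against scaled input at the summit for each peak (both log scales), in the sea urchin (left) and the sea star (right). Grey lines mark fold enrichments of 2, 5 and 20, and open circles mark peaks on scaffolds that hold the 10 highest −log10 q of the species. All 54 circled sea urchin peaks lie at the lowest background, 1.51 fragments, whereas 3 of the 26 circled sea star peaks lie at the genome-wide mean of 1.77.

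The 10 sea urchin peaks with the highest −log10 q lay on 5 scaffolds. The first was on Scaffold5086 at 71158 to 71631, with 163 ChIP fragments at its summit (95% Poisson interval 139 to 190) over a scaled input of 1.51, a fold enrichment of 65.2. A second peak on Scaffold5086, at 71964 to 72571, had 161 fragments and a fold enrichment of 64.4. On Scaffold4538, the peak at 12412 to 13073 had 144 fragments (121 to 170) and a fold enrichment of 57.7. The next was the peak on Scaffold19667 at 293 to 973, with 79 fragments and a fold enrichment of 31.8. The peak on Scaffold4538 at 4601 to 5113 had 78 fragments and a fold enrichment of 31.4. These 5 peaks also had the highest fold enrichments. The other five lay on Scaffold7987 at 7 to 704, on Scaffold4538 at 2399 to 2681 and at 10543 to 11357, on Scaffold16692 at 4 to 288, and on Scaffold5086 at 29831 to 30050. Their fold enrichments ran from 20.7 to 29.0.

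Scaffold5086 had the most sea urchin peaks, 37 between positions 703 and 72571, and held the widest one, 3238 bp at 703 to 3940. Scaffold4538 had 13 peaks between 1614 and 13073. On the 5 scaffolds together, the scaled input was at the genome-wide mean at all 54 peaks, so no window of input around them exceeded that mean. On all other sea urchin scaffolds this held for 126 of 3095 peaks, or 4.07%. Of the 23 sea urchin peaks with a fold enrichment of 10 or more, 18 lay on these 5 scaffolds. Without them, the highest sea urchin fold enrichment was 12.9, on Scaffold919 at 19051 to 19187, with 36 fragments (25.2 to 49.8). The highest −log10 q was then 33.0, on Scaffold47 at 291605 to 291788, with 69 fragments over a scaled input of 8.58. These peaks of the remaining scaffolds were chosen after their values were seen. The remaining 3095 peaks had a median fold enrichment of 4.13.

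The 10 sea star peaks with the highest −log10 q lay on 10 different scaffolds. The first was on Scaffold11110 at 8895 to 9029, with 67 fragments at its summit (51.9 to 85.1) over a scaled input of 1.77, a fold enrichment of 24.6. The peak on Scaffold3648 at 43227 to 43358 had 64 fragments (49.3 to 81.7) and a fold enrichment of 18.2. The peak on Scaffold11510 at 8842 to 8989 had 73 fragments and a fold enrichment of 13.2. The peak on Scaffold9002693 at 10 to 145, next to the start of its scaffold, had 54 fragments and a fold enrichment of 19.9. The peak on Scaffold1313 at 43583 to 43730 had 62 fragments and a fold enrichment of 16. Another, on Scaffold8870 at 2871 to 3001, also had 62 fragments, with a fold enrichment of 15.4. The peak on Scaffold7347 at 25448 to 25714 had 51 fragments and a fold enrichment of 18.2. The other three lay on Scaffold5733 at 24017 to 24187, on Scaffold868 at 13189 to 13327 and on Scaffold9824 at 9942 to 10081, with fold enrichments of 12.2, 10.8 and 10.8. The counting intervals of the 10 summits overlap, so their order by fragments is not resolved at this depth.

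The sea star scaffold with most peaks was Scaffold158, with 36 between 4169 and 155504. Its median peak had 72.5 fragments over a scaled input of 21.3, which is 12.1 times the genome-wide mean, and a fold enrichment of 3.39. Scaffold3405 followed with 29 peaks between 17755 and 36445, at a scaled input 21.2 times the mean. The widest sea star peak, 657 bp, was on Scaffold2718 at 43544 to 44200, with 137 fragments over a scaled input of 39.1. The 18 sea star scaffolds with 10 or more peaks had a median fold enrichment of 3.66 over their 282 peaks, against 6.16 on the other scaffolds. This was not so in the sea urchin, where the 603 peaks of 41 such scaffolds had a median of 4.27 against 4.12. Those 603 include the 37 peaks of Scaffold5086 and the 13 of Scaffold4538, with median fold enrichments of 6.76 and 9.94. The median without these 2 scaffolds was not computed.

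**Figure D3:**
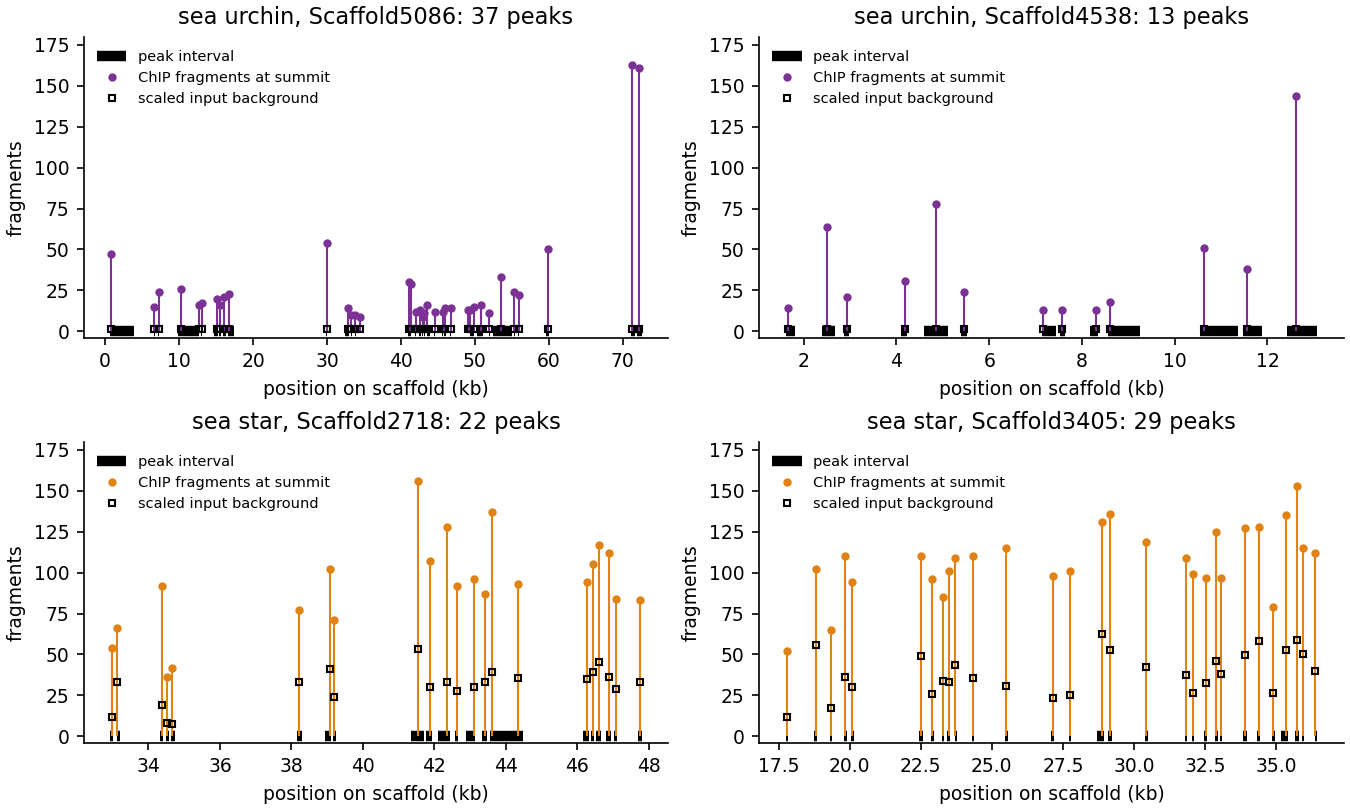
ChIP fragments at the summit (filled circles) and scaled input (open squares) of each peak along 2 sea urchin scaffolds (top) and 2 sea star scaffolds (bottom), with positions in kb and peak intervals as black bars at 0. On Scaffold5086 and Scaffold4538 the scaled input is at 1.51 fragments throughout, whereas the median on Scaffold2718 is 32.9 and on Scaffold3405 it is 37.5.

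Summits lay close together more often than random placement gave, in both species. In the sea urchin, 310 of 1733 pairs of neighbouring summits (17.9%) were at most 1000 bp apart, against a mean of 6.30% and a highest value of 7.62% in 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give). In the sea star, 967 of 3702 pairs (26.1%) were, against a mean of 14.6% and a highest value of 15.9% (one-sided permutation p = 0.001, again the smallest possible). The close pairs were thus 2.84 times and 1.79 times as frequent as under random placement. Without the scaffolds that hold the 10 highest −log10 q, these ratios were 3.21 in the sea urchin and 1.796 in the sea star, where this left out only 26 peaks. Among peaks with a −log10 q of 5 or more they were 1.81 in the sea urchin and 1.79 in the sea star, so the larger sea urchin ratio was not seen at that limit. In the sea star the excess lay at short gaps, with 222 pairs at 100 to 200 bp where random placement gave 67.9. At gaps of 1000 to 2000 bp the sea star had 301 pairs against 300.4 at random. In the sea urchin the excess reached further, with 201 pairs at 1000 to 2000 bp against 77.7. The 2 species differ in peak density and scaffold length, and the ratios were not tested against each other. Random placement ignores gaps in the assemblies and sequence where no read can be placed, both of which would raise the observed share of close pairs.

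**Figure D4:**
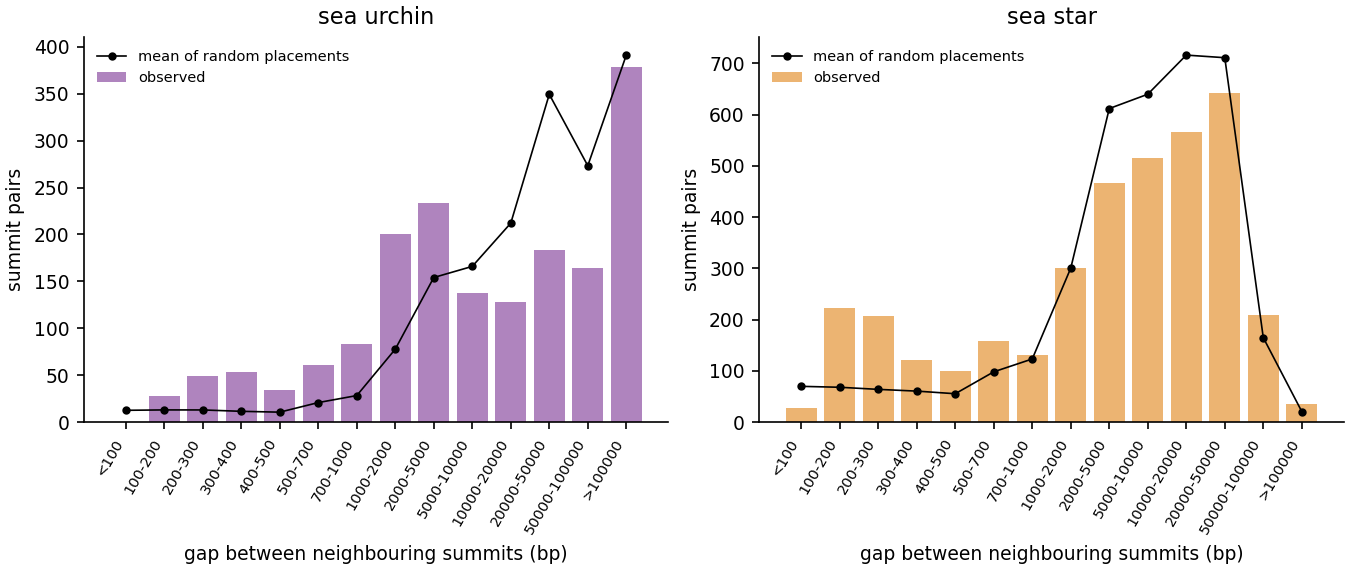
Pairs of neighbouring summits (vertical axis) by the gap between them in bp (horizontal axis, unequal bins) in the sea urchin (left) and the sea star (right). Bars are the observed pairs and black points the mean of random placements; at 100 to 200 bp the sea star has 222 pairs against 67.9 at random.

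Peaks with a neighbour within 1000 bp numbered 592 in the sea urchin (18.8%) and 2491 in the sea star (17.8%). The median fold enrichment was 4.21 for these and 4.13 for the others in the sea urchin. In the sea star it was 5.67 for peaks with a close neighbour and 6.22 for the others, and the median scaled input was 2.32 and 1.74 times the genome-wide mean.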

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

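The counts of sea star peaks stayed within 1.5 times of 13977 under the 9 alternatives run, from 9574 at a −log10 q of 10 or more upwards, but 3 of these could hardly have changed it: thinning, counting identical intervals once, since 0 intervals are shared in either list, and leaving out the scaffolds of the 10 highest −log10 q, which hold 26 peaks. The sea urchin count did not stay within that range: it fell from 3149 to 1352 at a −log10 q of 5 or more, to 276 at 10 or more, to 761 at a fold enrichment of 5 or more and to 1040 at a −log10 p of 10 or more, because fewer peaks meet the stricter limits. It was 2894 with intervals within 500 bp merged. Thinning the sea star fragments to the sea urchin depth left 13951 peaks at or above the lowest sea urchin −log10 p, but the sea star list was already cut above that limit, so this count says little about depth. Median fold enrichments rose with stricter limits: to 5.13 in the sea urchin at a −log10 q of 5 or more, to 6.53 in the sea urchin and 6.86 in the sea star at 10 or more, and to 8.12 in the 3149 sea star peaks with the highest −log10 q. On scaffolds with 2 or more peaks the sea star median was 6.09. Median widths became 162.5 bp in the sea urchin and 98 bp in the sea star at a −log10 q of 10 or more, 134 bp on sea urchin scaffolds with 2 or more peaks, and 108 bp in the sea star list cut to 3149. The excess of close summits kept its direction in the 5 alternatives per species that change the peaks or the distance, each with a permutation p at its floor of 0.001, which cannot show a weakening; in the sea star, leaving out 26 peaks could hardly have changed it. The ratios ran from 1.81 (−log10 q of 5 or more) to 3.21 in the sea urchin and from 1.20 to 2.14 in the sea star. They were not computed with intervals within 500 bp merged, so close summits inside 1 enriched region split into several peaks were not set apart. The alternatives at a −log10 p of 10, by scaffold, by scaled input and by thinning were chosen after seeing the data. No paired analysis was possible because each group has 1 library. For the same reason no replicate could be left out. The analyses of gene positions, binding sites, gene lists and shared genes were not run, since no genome of the builds was used here. Depth limits single peaks: a sea urchin peak at the median rests on 20 fragments. At the lowest −log10 p of each list, 1.97 Mb of the sea urchin genome and 5.59 Mb of the sea star genome reached that value by the deposited q-values, taking the strongest listed summit as the top-ranked base, while the peaks held 26.5% and 26.0% of that length, so most bases past the limit lay outside the listed intervals.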

Other observations

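The tests of thinning and of the span inside peaks were set before their results were seen, and the other tests below after. Ranking peaks by ChIP fragments in place of significance gave other regions. In the sea star, 3 of the 100 peaks with the highest −log10 q were also among the 100 with the most fragments at the summit, and in the sea urchin 40 were. The sea star peaks with the most fragments were on Scaffold2718 at 41347 to 41705 with 156, on Scaffold3405 at 35676 to 35811 with 153 and on Scaffold442 at 31362 to 31507 with 153, at fold enrichments of 2.88, 2.56 and 2.24. In the sea urchin, Scaffold518 followed Scaffold5086 and Scaffold4538 with 123 fragments at 505430 to 506011, over a scaled input of 29.7. These peaks were chosen after their values were seen. The median scaled input of the 100 peaks with most fragments was 24.4 times the genome-wide mean in the sea star and 9.63 times in the sea urchin. Sea star summits fell in the first 300 bases of a scaffold 808 times and in the next 300 bases 352 times, but 43 and 42 times on scaffolds with a summit past 10 kb.

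The strongest sea urchin signal lay on 5 scaffolds, with a scaled input at the genome-wide mean at 100% of their 54 peaks, most of which share 2 scaffolds. More copies of these sequences in the embryos than in the assembly would have raised the input along with the ChIP signal on these scaffolds, so that same observation argues against it. A second candidate explanation is DNA that was in the ChIP library and lacking from its input, such as a contaminant whose sequence is also in the assembly. Peaks were then expected to take up more of these scaffolds, from first to last peak, than of any other with 10 or more peaks. That expectation was not met: they took up 25.2% on Scaffold5086 and 39.4% on Scaffold4538, against 31.9% on Scaffold1453. The scaled input of Scaffold1453 was 11.3 times the mean, so that scaffold is covered densely in both libraries. The next, Scaffold376, had 13.04% and the rest less. Strong signal of any origin would also give wide and dense peaks, so these shares cannot tell this explanation from Tbr binding. Such DNA in the ChIP library stays open along with Tbr binding itself, for which no second antibody or control immunoprecipitation was analysed here. Only 4.07% of the 3095 peaks on other sea urchin scaffolds had a scaled input at the genome-wide mean. That share describes called peaks, and none was computed for sequence outside peaks. The 5 scaffolds were also picked by −log10 q, which is higher where the background is lower. The low input therefore does not weigh for or against Tbr binding.

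Sea star scaffolds with 10 or more peaks may hold repeated sequence that the assembly shows once. That explanation needs a raised input, and the median scaled input of the 18 scaffolds was 4.63 times that of the other 8473 (14.9 against 3.22 fragments; two-sided permutation p = 2e-05 on the difference of means, the smallest the 100000 resamples can give). It was more than 2 times that of the others on 13 of 18. Over peaks, the median scaled input of these sea star scaffolds was 10.5 times the genome-wide mean, against 1.78 times on the others. In the sea urchin it was 2.90 times against 2.64 times, so its 41 scaffolds with 10 or more peaks showed no such rise as a group. That group is mixed. Scaffold1453 stood at 11.3 times the mean, Scaffold5086 and Scaffold4538 at the mean, and Scaffold3 had 24 peaks spread over 2190 kb. The permutation test was set after its values were seen, so its p-value adds no separate support. It also does not say whether Tbr binds each copy of such a sequence. No biological explanation was tested for these scaffolds.

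The sea star list held 4.44 times as many peaks as the sea urchin list. A looser sea star threshold is argued against by the lists themselves, whose lowest −log10 p was 5.13 in the sea star and 3.99 in the sea urchin; at a common limit of 10 the ratio was 12.4. Deeper ChIP sequencing as the whole cause is argued against by thinning: with 0.749 of the sea star ChIP fragments kept at random, 9699 sea star peaks reached a −log10 p of 10 and the ratio fell from 12.4 to 9.33, so depth may account for a part; the share kept rests on the unstated genome sizes set in MACS2. The input, also deeper in the sea star, was scaled by the same share and not thinned, and the peak calling was not repeated. Antibody, developmental stage, genome assembly and a true difference in Tbr binding differ together between the 2 libraries, and the lists cannot separate them.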
